A study of Mus musculus with 6 samples.

How the data were processed

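Liver RNA from 6 samples was analysed, 3 labelled Ctrl and 3 labelled Fam210aHKO. Total RNA was extracted with TRIzol and mRNA was enriched on poly-T beads before library construction, per the labels. Samples were grouped by their titles. The genotype label of Fam210aHKO replicates 2 and 3 counts the gene number upward, and since the titles of all 3 read Fam210aHKO and Fam210a was lower in all 3, they were kept in that group. The labels number the samples in each group and do not say that each is a separate animal.

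The counts were deposited by the authors as whole numbers per Ensembl gene, 1 column per library, without normalization. The FPKM values were deposited by the authors per kilobase of the gene length in the table and per 1e6 of a library-specific size; that size, worked out from the values, was 60.1%, 55.4% and 59.4% of the count total in Ctrl and 86.3%, 82.8% and 81.6% in Fam210aHKO, and how it was set is not given in the sources used here. Per the submitters' processing notes FastQC, Trimmomatic, STAR, featureCounts and DESeq2 were used with the mouse build mm10, with no versions given. Strand setting and handling of multimapping reads are not given in the sources used here. Of the 54532 gene identifiers 54495 occur in GENCODE mouse release 21, and 53585 of those (98.3%) have the same coordinates there.

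Library totals were 13.0, 15.5 and 16.9 M counts (1 M is 1e6) in Ctrl replicates 1 to 3 and 17.6, 12.5 and 19.7 M in Fam210aHKO replicates 1 to 3. A count of 3 was between 0.153 and 0.239 CPM. Differences between replicates exceeded counting error, with a common biological coefficient of variation of 0.196.

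The comparison was Fam210aHKO against Ctrl, with group as the only factor, in edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM factors, and the quasi-likelihood F test of edgeR 4 was applied (two-sided, no fold threshold). P-values were adjusted by the Benjamini-Hochberg method over all 13706 tested genes, and an adjusted p under 0.05 made a call. Where counts are given as adjusted over the list alone, the adjustment ran over the members of that list. The standard error is the absolute log2 fold change divided by the square root of F. CPM values use TMM-scaled totals of the tested genes, except those of Xist and the lowest Ddx3y value, which use all counts. Principal components used log2 CPM (prior count 2) of the 500 most variable genes. For genes with 0 counts in a group, the bound sets that group at 3 counts in all; for 1 to 3 counts, a ratio of scaled totals is given with a 95% exact binomial interval.

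In all, 51 gene lists with 1127 entries were tested where at least 5 members passed the filter, which left 46. The set test was camera of limma 3.58.1 with the preset correlation of 0.01 between genes. Beside it stand camera with an estimated correlation and fry, both adjusted over the lists. For the cell type and sex lists an exact permutation test of the mean log2 CPM per library was added. Named genes were chosen by rule: 29 genes whatever their result (not all of them are used here), the 10 largest increases and 10 largest decreases among called genes with a mean of at least 1 CPM and no overlap between groups, and in each list up to 3 called members of smallest p in the main direction and up to 2 in the other, or the 2 most abundant where none was called. Design, lists, naming rule and alternatives were fixed before the data were examined.

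Replicate numbers are shared by the groups, so deviations from group means were correlated between libraries. Same-numbered libraries had correlations of 0.245, 0.182 and 0.155 and other pairs between -0.141 and -0.0262, so the numbers may pair the samples. A fit with the replicate number as an additive block was therefore run as an alternative. The main results come from the fit with group alone and do not use the pairing. What the pairing stands for is not given in the sources used here.

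Alternatives were median-of-ratios and upper-quartile scaling, library totals, library sizes without the 50 most abundant genes, no filter, a filter of CPM above 1 in 3 libraries, DESeq2 1.42.0, limma-voom, the legacy quasi-likelihood test with robust estimation, protein-coding genes only, limma on log2(FPKM + 1) and log2(FPKM + 0.1), stricter thresholds, leaving out each library in turn, and the replicate block. A fit without the genes standing apart in Fam210aHKO replicate 1 and without rRNA genes was added after the data were seen. On simulated data with 200 changed genes, edgeR recovered 83% of changes of 1 log2 unit and 100% of changes of 2, with 11 false calls among 194. The changed genes were drawn only from those of higher mean count, and as many were raised as lowered. No difference in scaling between the groups was simulated, whereas the real TMM factors averaged 0.855 in Ctrl and 1.17 in Fam210aHKO. The simulation thus does not cover errors of scaling. Shared sequence was tested with words of 31 bases from GENCODE transcripts in Python 3.11.15, and figures were drawn with matplotlib 3.10.9.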

Results

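Liver RNA from mice aged 5 weeks was profiled by RNA sequencing in 6 libraries, 3 from control animals (Ctrl) and 3 from animals with a hepatocyte-specific knockout of Fam210a (Fam210aHKO). FAM210A is a protein of the mitochondrial inner membrane. The comparison asks how its loss from hepatocytes changes gene expression in the juvenile liver. Messenger RNA was selected on poly-T beads, per the labels, and each library had between 12.5 and 19.7 M counts (1 M is 1e6) over 54532 annotated genes. Of these, 13706 passed the filter on low counts and were tested. The labels number the samples within each group without saying that each came from a separate animal, so the p-values measure the spread between these samples, part of which may be technical. The genotype label of Fam210aHKO replicates 2 and 3 carries other gene numbers than Fam210a, and the sample titles, which name Fam210aHKO for all 3, were used to form the groups.

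Fam210a mRNA fell to 25.1% of the control level. The gene lies on chromosome 18 from 68260187 to 68300333 (mm10). Its level was 119, 136 and 162 CPM (counts per 1e6, scaled by TMM factors) in Ctrl replicates 1 to 3 and 31.7, 28.6 and 44.2 CPM in Fam210aHKO replicates 1 to 3, so the groups did not overlap. The fitted log2 fold change was -1.99 (SE 0.194, adjusted p = 4.42e-05, edgeR quasi-likelihood test). Counts cover the whole gene, and the deleted part is not given in the sources used here, so the remaining level does not measure how many hepatocytes kept the gene. The related gene Fam210b fell as well, from 163 ± 25.7 to 70.1 ± 12.3 CPM (mean ± SD, n = 3 per group), a log2 fold change of -1.22 (SE 0.173, adjusted p = 0.000481).

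The knockout livers differed from the controls across a large part of the transcriptome. Most of the tested stress genes induced by ATF4 (34 of 40) and cell cycle genes (31 of 39) rose. So did most markers of monocyte-derived and lipid-associated macrophages (10 of 17). Under TMM scaling, most genes of the urea cycle and amino acid catabolism (21 of 28) and most interferon-stimulated genes (22 of 32) fell. Most hepatocyte secreted proteins and transcription factors (19 of 29) and male-biased genes (20 of 22) fell as well. With library totals in place of TMM factors, 14 of 28, 14 of 32, 14 of 29 and 20 of 22 were lower. Under TMM scaling all of these lists, higher and lower, were called by camera at its preset correlation. With an estimated correlation none of them was called (lowest adjusted p = 0.0988). In all, 1922 genes were higher and 1852 lower in Fam210aHKO at an adjusted p under 0.05, 27.5% of those tested. Of them 1052 and 950 changed by at least 2-fold. At an unadjusted p under 0.05 there were 5322 genes. For 5852 of the 13706 tested genes the CPM of the groups did not overlap, where chance alone gives 10% with 3 libraries against 3. On the 500 most variable genes, principal component 1 held 88.0% of the variance and separated the groups, from -43.4 to -38.3 in Ctrl and from 38.2 to 43.3 in Fam210aHKO.

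**Figure D1:**
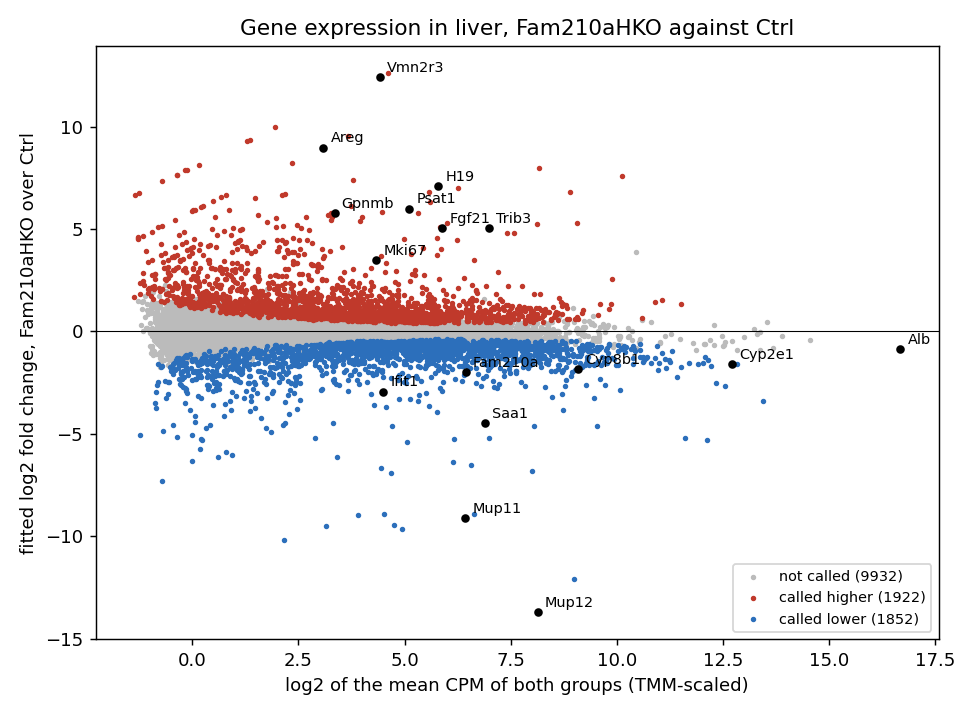
Fitted log2 fold change (Fam210aHKO over Ctrl) of each of the 13706 tested genes against the log2 of its mean CPM. Red points are the 1922 genes called higher, blue points the 1852 called lower and grey points the rest; black points are named genes, among them Fam210a at -1.99.

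The balance of higher and lower genes depends on the scaling. TMM factors averaged 0.855 in Ctrl and 1.17 in Fam210aHKO, and with library totals in their place the median log2 fold change of the tested genes shifted by 0.45. The calls were then 5846 higher and 868 lower, so that 87.1% of calls were higher against 50.9% with TMM. All changes below are relative to the typical gene under TMM scaling. For a list whose direction turns with library totals, that value stands beside it.

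Most genes of the integrated stress response, which ATF4 drives when mitochondria or translation are disturbed, rose. Of 40 measured members, 34 rose, 1 fell and 5 did not pass (35 and 2 adjusted over the list alone), with a median log2 fold change of 1.92. The list was called higher by camera (adjusted p = 2.02e-28) but not when the correlation between its genes was estimated (adjusted p = 0.104 with an estimated correlation). Atf4 itself rose from 65.8 ± 1.20 to 149 ± 20 CPM. Psat1, of serine synthesis, rose from 1.05 ± 0.427 to 67.7 ± 26.3 CPM (log2 fold change 5.99, SE 0.382, adjusted p = 3.66e-06). The pseudokinase Trib3 rose from 7.58 ± 1.59 to 247 ± 104 CPM and the hormone Fgf21 from 3.48 ± 1.28 to 115 ± 40.9 CPM, with log2 fold changes of 5.03 and 5.05. The transcription factor Ddit3 (log2 fold change 4.08, SE 0.381), the secreted factor Gdf15 (4.11, SE 0.372), Asns (2.35, SE 0.308) and Mthfd2 (3.06, SE 0.458) rose too, each with an adjusted p of at most 0.000667. The 1 member that fell was Cth, of cysteine synthesis (log2 fold change -0.84, adjusted p = 0.00622; 0.104 with library totals). Members of the NRF2 antioxidant list also rose more often than they fell, with 14 of 29 higher and 2 lower (15 and 4 adjusted over the list alone) and camera adjusted p = 3.56e-05 (adjusted p = 0.365 with an estimated correlation). Srxn1 rose from 62.8 ± 2.54 to 222 ± 30.6 CPM and the transporter Abcc4 from 3.28 ± 0.678 to 111 ± 20.8 CPM, while Gsta3 fell from 974 ± 70.3 to 584 ± 114 CPM (not called without Fam210aHKO replicate 2, adjusted p = 0.0732, or with library totals, 0.237). Of 23 p53 target and apoptosis genes 12 rose and 0 fell (13 and 0 adjusted over the list alone), with camera adjusted p = 1.88e-08 (adjusted p = 0.0988 with an estimated correlation). Phlda3 rose from 0.968 ± 0.140 to 15.6 ± 1.27 CPM, and the death receptor gene Tnfrsf10b from 0.303 ± 0.0877 to 5.67 ± 0.936 CPM. Cdkn1a, the best known p53 target, did not pass (94.9 ± 32.7 and 112 ± 10.7 CPM, adjusted p = 0.482), but was called higher with library totals (log2 fold change 0.69, adjusted p = 0.0258). Endoplasmic reticulum chaperones and unfolded protein response genes had 1 member higher and 7 lower of 22 (1 and 11 adjusted over the list alone). Its median of -0.43 turned to 0.02 with library totals (3 higher and 1 lower). That list missed the threshold (camera adjusted p = 0.0513), and with the replicate number as a block 12 members were lower and the list was called (adjusted p = 0.0282), as it was with limma-voom (0.0118), with no filter (0.0219) and with protein-coding genes alone (0.0328). It was also called without Ctrl replicate 2 (adjusted p = 0.00502), Fam210aHKO replicate 1 (0.0396) or Fam210aHKO replicate 3 (0.0248), and leaving out Ctrl replicates 1 to 3 and Fam210aHKO replicates 1 to 3 in turn 4, 10, 1, 4, 2 and 7 members were lower. Edem1 fell from 147 ± 22.2 to 84.6 ± 10 CPM (adjusted p = 0.123 with library totals) and Atf6 rose from 89.9 ± 12.2 to 146 ± 15.9 CPM.

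**Figure D2:**
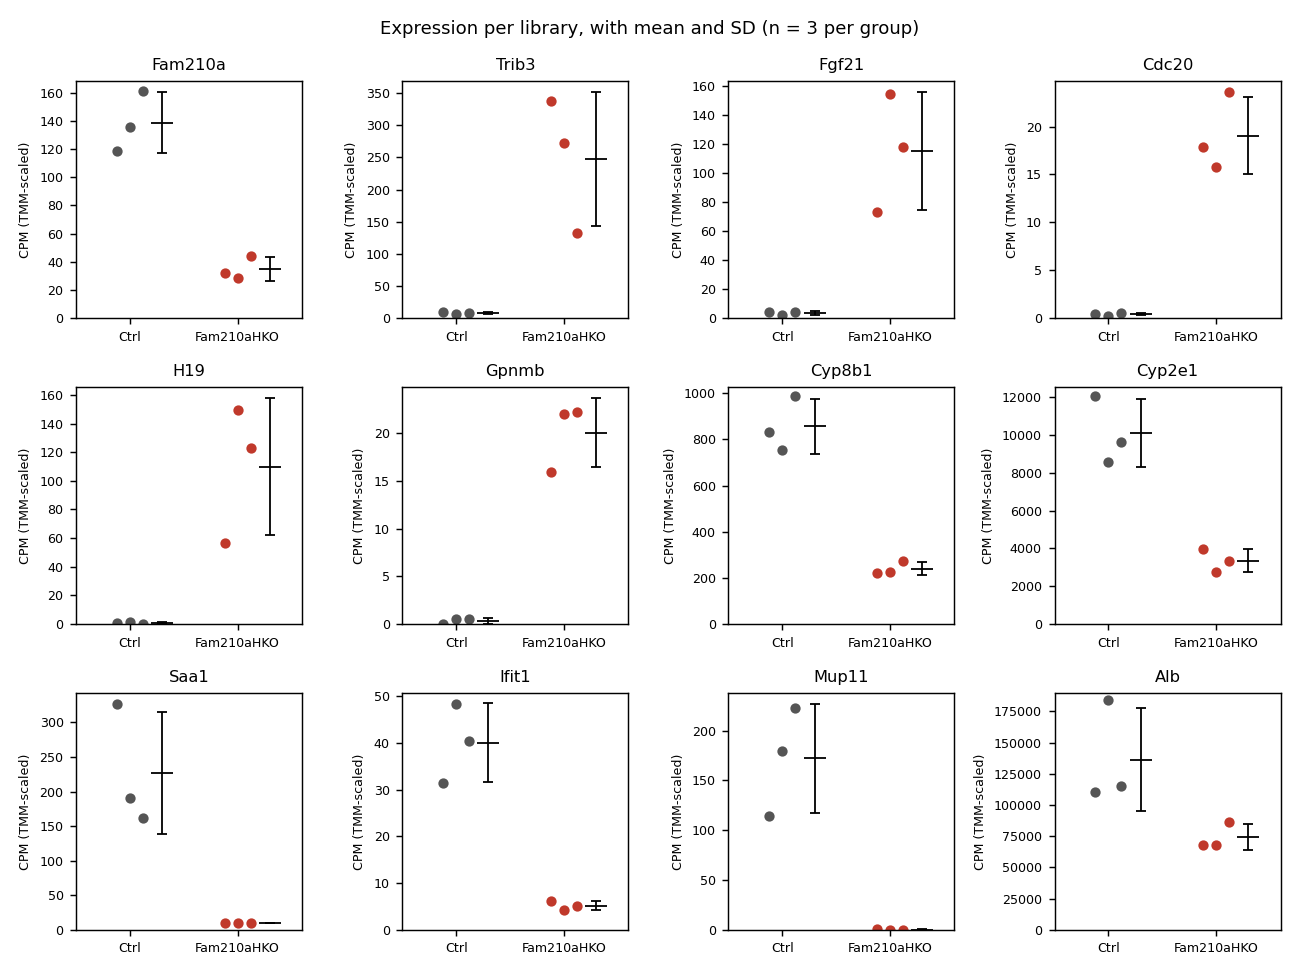
CPM (TMM-scaled) of 12 genes in each library, Ctrl in grey and Fam210aHKO in red, with the mean and SD of each group in black (n = 3). Fam210a lies between 119 and 162 CPM in Ctrl and between 28.6 and 44.2 CPM in Fam210aHKO; Trib3, Fgf21, Cdc20, H19 and Gpnmb are higher and Cyp8b1, Cyp2e1, Saa1, Ifit1 and Mup11 lower in Fam210aHKO, while Alb did not pass the test.

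Under TMM scaling, the messages for the respiratory chain encoded in mitochondria were not called, and part of those encoded in the nucleus fell. Of the 13 mitochondrially encoded mRNAs 0 were called by edgeR, also when adjusted over the list alone, and the set was not called by camera (adjusted p = 0.994); with the replicate block 2 were higher. Their most abundant message, mt-Co1, stood at 27850 ± 6440 CPM in Ctrl and 20581 ± 3686 CPM in Fam210aHKO (adjusted p = 0.528), and mt-Cytb at 16282 ± 3415 and 13974 ± 1508 CPM (adjusted p = 0.717). The median of this list was -0.07 (between -0.15 and 0.02 without single libraries), its mean 0.03 and its median with library totals 0.38. With library totals 3 of its members were higher and 0 lower. Nuclear complex I genes had 0 members higher and 7 lower of 36 (0 and 6 adjusted over the list alone), a median of -0.30 that turned to 0.16 with library totals, and camera adjusted p = 0.0102 (adjusted p = 0.811 with an estimated correlation). Ndufa3 fell from 99.6 ± 19.5 to 56.4 ± 3.78 CPM and Ndufb3 from 48.6 ± 5.5 to 29.8 ± 5.97 CPM, calls that library totals ended (adjusted p = 0.0933 and 0.273). The complex I call was lost with library totals (adjusted p = 0.0641; 2 members higher and 0 lower) and with fry (0.216). It was also lost without Ctrl replicate 1 (adjusted p = 0.0834, 2 members lower) or Fam210aHKO replicate 3 (adjusted p = 0.148, 4 members lower). Further, 11 members were lower without Ctrl replicate 3 and 3 without Ctrl replicate 2, and 16 were lower with the replicate block. Complexes II and III had 6 of 14 members lower, complex IV 4 of 13 and ATP synthase 5 of 18, with 1 higher in the last (7, 4 and 7 lower adjusted over each list alone). These 3 lists were not called (camera adjusted p = 0.064, 0.103 and 0.0825), but were called with limma-voom (0.0127, 0.0293 and 0.0225), and complexes II and III also with no filter (0.039) and with protein-coding genes alone (0.0459). Their medians of -0.41, -0.45 and -0.35 turned to 0.05, 0.01 and 0.11 with library totals. Each was called without Ctrl replicate 3 (adjusted p = 0.01, 0.01 and 0.00661) or without Fam210aHKO replicate 2 (adjusted p = 0.0321, 0.0489 and 0.0321). Leaving out Ctrl replicates 1 to 3 and Fam210aHKO replicates 1 to 3 in turn, the lower members numbered 1, 3, 6, 4, 3 and 2 for complexes II and III, 1, 2, 6, 2, 1 and 1 for complex IV and 2, 3, 9, 3, 2 and 2 for ATP synthase. With the replicate block 9 ATP synthase genes were lower. Atp5k fell from 53.4 ± 9.81 to 27.7 ± 3.18 CPM (log2 fold change -0.95, adjusted p = 0.00216).

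Other mitochondrial groups had few members called under TMM, and more called higher with library totals. With library totals 42 ribosomal proteins were higher and 0 lower, 13 and 0 of the translation factors and synthetases, 9 and 1 of the DNA maintenance genes, 16 and 0 of the chaperones and proteases, 6 and 1 of the dynamics genes, and 8 and 0 of the tricarboxylic acid cycle enzymes. Mitochondrial ribosomal proteins had 6 members higher and 5 lower of 77 (3 and 0 adjusted over the list alone; camera adjusted p = 0.829), among them Mrps18b with 13.6 ± 2.03 and 25.8 ± 4.37 CPM and Mrpl49 with 27.6 ± 4.57 and 17.5 ± 1.83 CPM (not called without Ctrl replicate 1, adjusted p = 0.0554, or with library totals, 0.371). Leaving out each library in turn, in the order of the labels with Ctrl first, ribosomal members higher numbered 4, 5, 3, 3, 3 and 7 and members lower 0, 3, 3, 1, 2 and 2. Translation factors and aminoacyl-tRNA synthetases had 5 of 28 higher and 0 lower (4 and 0 adjusted over the list alone; camera adjusted p = 0.486). Tars2 rose from 17.2 ± 1.62 to 27.6 ± 3.38 CPM. Lars2 is also among the 5, but its call rests on Fam210aHKO replicate 1, which had 3080 CPM against 23.3 to 29.2 CPM in the other 5 libraries. Leaving out Ctrl replicates 1 to 3 and Fam210aHKO replicates 1 to 3 in turn, 2, 3, 1, 2, 2 and 5 of these members were higher. Tufm, the mitochondrial elongation factor that binds FAM210A, stood at 85.8 ± 16.7 and 85.9 ± 5.41 CPM (log2 fold change 0.00, SE 0.161). DNA maintenance and transcription genes had 2 higher and 1 lower of 23 (camera adjusted p = 0.913), chaperones and proteases 2 higher and 1 lower of 23 (0.394), dynamics, cristae and mitophagy genes 3 higher and 3 lower of 20 (0.558), and tricarboxylic acid cycle enzymes 2 higher and 2 lower of 18 (0.886); the counts adjusted over the list alone were the same in these 4. The medians of the dynamics and cycle lists, -0.16 and -0.06, turned to 0.29 and 0.40 with library totals and lay between -0.23 and -0.06 and between -0.15 and 0.03 without single libraries, and the cycle list's mean was 0.05. Leaving out each library in turn, in the same order, DNA maintenance members higher numbered 1, 3, 1, 1, 2 and 4 and dynamics members lower 2, 3, 1, 1, 1 and 1. With the replicate block these 4 lists had 4 and 2, 4 and 1, 3 and 5, and 4 and 4 members higher and lower. The protease Lonp1 rose from 129 ± 17.8 to 458 ± 91.8 CPM (log2 fold change 1.83, adjusted p = 6.2e-05) and the chaperone Hspa9 from 586 ± 20.9 to 1230 ± 240 CPM. Citrate synthase (Cs) rose from 110 ± 8.67 to 262 ± 47.6 CPM and the autophagy receptor Sqstm1 from 444 ± 32.1 to 1110 ± 166 CPM. The mitophagy receptor Bnip3 fell from 189 ± 36.2 to 72.3 ± 7.90 CPM and Hsd17b10 from 319 ± 54.4 to 123 ± 26.2 CPM. The protease gene Oma1 and the fusion gene Opa1 did not pass (log2 fold changes 0.17, SE 0.174, and -0.28, SE 0.141), though Oma1 was called higher with library totals (0.62, adjusted p = 0.0186).

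With TMM, most measured members fell in the lists of urea cycle and amino acid catabolism, bile acids, cytochrome P450 genes and hepatocyte secreted proteins. With library totals, members lower in these lists numbered, in that order, 14 of 28, 11 of 22, 12 of 27 and 14 of 29. Members higher numbered 0, 1, 4 and 1. The medians were then -0.51, -0.81, -0.46 and -0.42, against -0.96, -1.26, -0.94 and -0.88 with TMM. Of 28 urea cycle and amino acid catabolism genes 21 fell and 0 rose (22 and 0 adjusted over the list alone), with camera adjusted p = 5.83e-13 (adjusted p = 0.0988 with an estimated correlation). Hal, which degrades histidine, fell from 798 ± 17.0 to 176 ± 30.7 CPM and Sds, which degrades serine, from 137 ± 22.4 to 25.9 ± 6.55 CPM. Bile acid synthesis and transport had 14 of 22 members lower and 0 higher (16 and 0 adjusted over the list alone), with camera adjusted p = 1.2e-10 (adjusted p = 0.0988 with an estimated correlation). Cyp8b1, which sets the share of cholic acid, fell from 858 ± 119 to 239 ± 28.4 CPM (log2 fold change -1.85, adjusted p = 4.35e-05). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 185 ± 74.9 and 70.3 ± 45.6 CPM (log2 fold change -1.40, SE 0.475, adjusted p = 0.0491). That call was lost with DESeq2 (adjusted p = 0.165), library totals (0.108), upper-quartile scaling (0.0527), the filter of CPM above 1 (0.0507), the legacy quasi-likelihood test (0.225) and FPKM, and without any of Ctrl replicates 1, 2 and 3 or Fam210aHKO replicate 2 (0.067, 0.163, 0.0667 and 0.0739). Cytochrome P450 and xenobiotic genes had 17 of 27 lower and 1 higher (19 and 1 adjusted over the list alone), with camera adjusted p = 5.74e-08 (adjusted p = 0.161 with an estimated correlation). Cyp2f2 fell from 787 ± 82.4 to 197 ± 17.5 CPM and Cyp2c55 rose from 1.44 ± 0.532 to 6.66 ± 1.15 CPM. Hepatocyte secreted proteins and transcription factors had 19 of 29 lower and 0 higher (20 and 0 adjusted over the list alone), with camera adjusted p = 1.18e-10 (adjusted p = 0.0988 with an estimated correlation). Serpina1c fell from 1463 ± 159 to 237 ± 25.4 CPM and clotting factor F9 from 361 ± 37.8 to 131 ± 19.3 CPM. Albumin (Alb) did not pass, at 136499 ± 41080 and 74313 ± 10600 CPM (log2 fold change -0.88, SE 0.791, adjusted p = 0.449), though DESeq2, limma-voom and the legacy quasi-likelihood test called it lower (adjusted p = 0.000289, 0.0338 and 0.0171).

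Periportal and pericentral genes mark both ends of the liver lobule. The periportal list had 10 of 20 members lower and 3 higher (12 and 3 adjusted over the list alone), with camera adjusted p = 7.41e-06 (adjusted p = 0.0988 with an estimated correlation), and 14 of its members stand in other lists too. Apoa4 rose from 242 ± 33.7 to 608 ± 183 CPM. The pericentral list had 9 of 20 lower and 1 higher (9 and 2 adjusted over the list alone), a median of -0.40 that turned to 0.05 with library totals (3 higher and 2 lower), and camera adjusted p = 0.0372 (adjusted p = 0.682 with an estimated correlation). Its call was lost with fry (adjusted p = 0.0843) and without Ctrl replicate 1 (adjusted p = 0.13) or Fam210aHKO replicate 2 (0.0702). Cyp2e1, a pericentral enzyme, fell from 10107 ± 1803 to 3360 ± 593 CPM and Cyp27a1 from 493 ± 26.0 to 178 ± 38.0 CPM. Of 27 gluconeogenesis, glycolysis and glycogen genes 13 fell and 2 rose (15 and 3 adjusted over the list alone), with camera adjusted p = 0.0171 (adjusted p = 0.427 with an estimated correlation). With library totals the balance turned to 6 lower and 8 higher, with a median of -0.23 against -0.66. Pck1, the key enzyme of gluconeogenesis, fell from 3516 ± 804 to 1316 ± 328 CPM (log2 fold change -1.42, adjusted p = 0.00339), and Igfbp1 rose from 272 ± 17.3 to 1616 ± 232 CPM.

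Genes of lipid handling moved apart. Plin2, a coat protein of lipid droplets, rose from 1038 ± 432 to 2771 ± 509 CPM (log2 fold change 1.42, adjusted p = 0.00533), Cidec, which enlarges droplets, from 24.2 ± 21.5 to 146 ± 47.0 CPM (2.59, adjusted p = 0.00287; 0.0618 with the legacy quasi-likelihood test) and the fatty acid transporter Cd36 from 117 ± 20.5 to 235 ± 72.2 CPM (1.01, adjusted p = 0.00755; 0.104 with unfiltered FPKM). Lipid droplet proteins and lipases as a list had 5 higher and 4 lower of 19 (6 and 4 adjusted over the list alone; camera adjusted p = 0.829), with a median of -0.02 (between -0.10 and 0.05 without single libraries), a mean of 0.19 and a median of 0.44 with library totals. De novo lipogenesis had 2 higher and 7 lower of 23 (3 and 7 adjusted over the list alone), a median of -0.09 (between -0.23 and -0.08 without single libraries) that turned to 0.36 with library totals (7 higher and 6 lower), and camera adjusted p = 0.0488 (adjusted p = 0.572 with an estimated correlation). That call was lost with library totals (adjusted p = 0.0606), with limma-voom (0.0842), with fry (0.0537), with the filter of CPM above 1 (0.0508) and without Ctrl replicate 3 (0.126) or Fam210aHKO replicate 2 (0.0777). With the replicate block 5 members were higher and 9 lower. Srebf1, a main regulator of fatty acid synthesis, fell from 53.1 ± 21.3 to 21.4 ± 5.80 CPM (adjusted p = 0.00604; 0.081 with unfiltered FPKM). Fasn fell from 137 ± 35.0 to 72.6 ± 20.1 CPM (adjusted p = 0.0112; 0.113 with library totals and 0.0771 with unfiltered FPKM), while Me1 rose from 124 ± 24.5 to 224 ± 12.8 CPM. The desaturase gene Scd1 did not pass (1088 ± 147 and 721 ± 281 CPM, adjusted p = 0.117), but passed with the replicate block (log2 fold change -0.66, adjusted p = 0.0486) and without Fam210aHKO replicate 3 (adjusted p = 0.0077).

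Lipid uptake, transport and lipoprotein secretion had 6 higher and 12 lower of 31 (6 and 14 adjusted over the list alone), with camera adjusted p = 0.0255 (adjusted p = 0.637 with an estimated correlation). With library totals 8 were higher and 8 lower, with a median of -0.07 against -0.53. With the replicate block this list was not called (adjusted p = 0.06), nor was it without Ctrl replicate 1 (0.0856), Fam210aHKO replicate 1 (0.0565) or Fam210aHKO replicate 2 (0.0617), nor by fry (0.0537). Apoc3 fell from 2017 ± 243 to 675 ± 30.3 CPM, and the lipoprotein receptor gene Vldlr rose from 6.16 ± 1.61 to 26.9 ± 6.06 CPM. Mitochondrial fatty acid oxidation and ketogenesis had 0 higher and 5 lower of 24 (also 0 and 5 adjusted over the list alone), a median of -0.33 that turned to 0.12 with library totals (4 higher and 0 lower), and camera adjusted p = 0.0324 (adjusted p = 0.572 with an estimated correlation). Without Ctrl replicate 1 or Fam210aHKO replicate 1 it was not called (adjusted p = 0.07 and 0.0606), nor with library totals (0.091), and with the replicate block 10 members were lower. Acat1 fell from 623 ± 17.9 to 341 ± 20.1 CPM (adjusted p = 0.00161; 0.0522 with library totals). Cpt1a, which admits fatty acids to mitochondria, stood at 856 ± 128 and 849 ± 80.2 CPM (adjusted p = 0.972). PPARalpha targets had 5 higher and 10 lower of 28 (6 and 10 adjusted over the list alone; camera adjusted p = 0.387), with a median of -0.31 that turned to 0.14 with library totals (9 higher and 2 lower). Ppara itself fell from 160 ± 38.6 to 78.3 ± 30.7 CPM (adjusted p = 0.012; 0.0515 without Ctrl replicate 3, 0.0786 with library totals and 0.0752 with unfiltered FPKM). Acot2 rose from 13.3 ± 5.22 to 369 ± 91.7 CPM and Pdk4, which restrains glucose oxidation, from 16.3 ± 4.94 to 183 ± 73.2 CPM. Cholesterol synthesis genes had 3 higher and 6 lower of 23 (4 and 8 adjusted over the list alone; camera adjusted p = 0.332), with a median of -0.08 (between -0.27 and -0.08 without single libraries) that turned to 0.39 with library totals (8 higher and 2 lower), and 3 were lower without Fam210aHKO replicate 2.

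Most cell cycle genes and some fetal liver genes rose. Of 39 cell cycle genes 31 rose and 1 fell (33 and 1 adjusted over the list alone), with a median log2 fold change of 2.75 and camera adjusted p = 6.23e-32 (adjusted p = 0.0988 with an estimated correlation). Mki67, the usual marker of dividing cells, rose from 3.30 ± 1.89 to 37.1 ± 12.1 CPM (log2 fold change 3.49, adjusted p = 8.11e-05) and Cdc20 from 0.383 ± 0.122 to 19.1 ± 4.06 CPM. Tk1, of thymidine salvage, was the 1 member that fell, from 14.7 ± 2.53 to 5.25 ± 2.22 CPM. Fetal and perinatal liver genes had 6 of 13 higher and 0 lower (7 and 0 adjusted over the list alone), with camera adjusted p = 6.71e-07 (adjusted p = 0.136 with an estimated correlation). The fetal RNA H19 rose from 0.811 ± 0.556 to 110 ± 47.9 CPM, Igf2bp3 from 3.76 ± 0.257 to 16.0 ± 1.38 CPM and alpha-fetoprotein (Afp) from 1.95 ± 0.514 to 11.5 ± 3.11 CPM. Immediate early genes had 7 of 17 higher and 1 lower (also 7 and 1 adjusted over the list alone), with camera adjusted p = 0.000196 (adjusted p = 0.318 with an estimated correlation). Atf3 rose from 1.43 ± 0.219 to 78.5 ± 46.2 CPM and Myc from 3.10 ± 0.742 to 40.3 ± 20.6 CPM. Circadian clock genes had 2 of 19 lower and 0 higher (1 and 0 adjusted over the list alone; camera adjusted p = 0.235), and 8 lower and 2 higher with the replicate block. With library totals 1 was lower and 2 were higher, with a median of -0.02 against -0.46. Without Fam210aHKO replicate 1, 4 were lower, and without Ctrl replicate 3 or Fam210aHKO replicate 2, 1 was. Hlf fell from 59.4 ± 6.87 to 23.1 ± 1.94 CPM.

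The largest decreases were in male-biased liver genes, most of them major urinary proteins (Mup). Of 22 measured members 20 fell and 0 rose (also 20 and 0 adjusted over the list alone), with a median log2 fold change of -5.19 and camera adjusted p = 5e-55 (adjusted p = 0.0988 with an estimated correlation). Mup genes together took between 0.847% and 1.19% of the counts in Ctrl and between 0.0221% and 0.0411% in Fam210aHKO. By fitted log2 fold change the 10 largest decreases were those of Mup12, Mup7, Mup1, Mup15, Mup19, Mup11, Mup14, Hsd3b5, Mup17 and Mup21, all with an adjusted p of at most 9.14e-05. Mup11 fell from 172 ± 54.5 to 0.285 ± 0.206 CPM and the steroid enzyme gene Hsd3b5 from 45.8 ± 28.6 to 0.0994 ± 0.0927 CPM. Mup1 had 364 counts in Ctrl and 0 in Fam210aHKO, which is at least 183-fold lower against a floor of 3 counts over the group, and Mup12 had 22702 and 2 counts, a ratio of 17083 (95% exact interval 4729 to 141070, counting error only). Mup genes are near-identical, so the split of reads between them is uncertain. Female-biased genes had 15 of 26 higher and 2 lower (17 and 2 adjusted over the list alone), with a median of 1.84 (also with the member at 0 counts in Ctrl set at its bound) and camera adjusted p = 2.24e-06 (adjusted p = 0.365 with an estimated correlation). Cyp3a44 rose from 0.850 ± 0.275 to 93.9 ± 67.5 CPM and Prom1 from 1.23 ± 0.131 to 6.30 ± 0.860 CPM, while Rdh16f2 fell from 120 ± 11.1 to 67.8 ± 8.69 CPM (adjusted p = 0.083 with library totals). All 6 libraries had the profile of male mice. Xist was at most 6 counts in any library, and the Y-linked Ddx3y stood at 119 ± 18.8 and 104 ± 13 CPM. Of 4 sex-linked genes measured 0 were called, also when adjusted over the list alone; their median was -0.23 (between -0.35 and -0.11 without single libraries), and 0.23 with library totals.

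The 10 largest increases by fitted log2 fold change were those of Cyp3a41a, Vmn2r3, Cyp3a41b, Coro6, Areg, Bex2, Gipc2, mt-Rnr1, Wfdc3 and H19. In 4 of these the Ctrl libraries had 0 counts, and against a floor of 3 counts over the group Vmn2r3 was at least 527-fold, Cyp3a41a at least 519-fold, Coro6 at least 66.4-fold and Gipc2 at least 26.8-fold higher. Vmn2r3, a vomeronasal receptor gene on chromosome 3 from 64257215 to 64289709, had 795, 811 and 775 counts in Fam210aHKO replicates 1 to 3. Whether these reads came from the gene itself or from an introduced construct was not tested, so the bound holds for the reads assigned to it. Areg, which encodes the growth factor amphiregulin, had 1 count in Ctrl and 993 in Fam210aHKO, a ratio of 660 (95% exact interval 118 to 26087), Bex2 had 1 and 584, a ratio of 388 (69.4 to 15353), and Cyp3a41b had 1 and 1224, a ratio of 813 (146 to 32149). These intervals cover counting error only, not the spread between libraries, which for Areg ran from 8.16 to 29.2 CPM in Fam210aHKO. Wfdc3 rose from 0.163 ± 0.0968 to 27.6 ± 20.1 CPM. Cyp3a41a and Cyp3a41b are near-identical, so their split of reads is uncertain, and the Cyp3a41a call was lost with the legacy quasi-likelihood test (adjusted p = 0.156). The mt-Rnr1 value rests on Fam210aHKO replicate 1 (1704 CPM, at most 7.29 CPM elsewhere), and its call was lost with limma-voom (adjusted p = 0.323), with the legacy quasi-likelihood test (0.157), with FPKM, with the replicate block (log2 fold change 3.56, adjusted p = 0.0682) and without Ctrl replicate 1 or 3 (adjusted p = 0.0551 and 0.0561).

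Most interferon-stimulated and acute phase genes fell. Of 32 interferon-stimulated genes 22 fell and 0 rose (23 and 1 adjusted over the list alone), with a median of -0.98 (-0.53 with library totals, 14 lower and 1 higher) and camera adjusted p = 3.51e-14 (adjusted p = 0.104 with an estimated correlation). Ifit1 fell from 40 ± 8.47 to 5.17 ± 0.901 CPM and Irgm1 from 81.1 ± 5.26 to 26.2 ± 2.34 CPM. The acute phase list had 18 of 27 members lower and 2 higher (19 and 2 adjusted over the list alone), with camera adjusted p = 6.08e-10 (adjusted p = 0.104 with an estimated correlation). Serum amyloid Saa1 fell from 227 ± 88.0 to 10.1 ± 0.334 CPM and Orm1 from 669 ± 133 to 179 ± 37.7 CPM, whereas Apcs rose from 83.4 ± 26.3 to 233 ± 32.2 CPM. Inflammatory cytokines and chemokines had 5 of 18 members higher and 0 lower (5 and 1 adjusted over the list alone). This list missed the threshold (camera adjusted p = 0.064) and passed it with the replicate block (adjusted p = 0.0417), with no filter (0.00663), with fry (0.0425) and without Ctrl replicate 2 (0.0264), Fam210aHKO replicate 1 (0.0344) or Fam210aHKO replicate 2 (0.0451). Without Ctrl replicate 1, Fam210aHKO replicate 2 or Fam210aHKO replicate 3, 3 members were higher. Tnfrsf12a, the receptor of the cytokine TWEAK, rose from 8.43 ± 2.35 to 68.1 ± 13.3 CPM.

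Markers of other liver cells did not move together. Monocyte-derived and lipid-associated macrophage markers had 10 of 17 higher and 0 lower (also 10 and 0 adjusted over the list alone), with camera adjusted p = 1.2e-10 (adjusted p = 0.0988 with an estimated correlation). Gpnmb rose from 0.346 ± 0.304 to 20 ± 3.61 CPM, Mmp12 from 0.347 ± 0.127 to 7.56 ± 1.5 CPM and Cd63 from 6.52 ± 1.86 to 144 ± 36.3 CPM. Kupffer cell markers had 1 of 15 higher and 1 lower (also 1 and 1 adjusted over the list alone; camera adjusted p = 0.886), and 6 higher and 0 lower with library totals. Cholangiocyte and ductular reaction markers had 10 of 19 higher and 0 lower (13 and 0 adjusted over the list alone), with camera adjusted p = 1.35e-08 (adjusted p = 0.104 with an estimated correlation). Krt23 rose from 4.38 ± 1.64 to 29.0 ± 5.70 CPM. Extracellular matrix and fibrosis genes had 17 of 31 higher and 0 lower (23 and 1 adjusted over the list alone), with camera adjusted p = 2.24e-06 (adjusted p = 0.546 with an estimated correlation; 0.0537 with fry). With library totals 29 were higher. Of its members 9 and 11 were higher without Ctrl replicate 3 and without Fam210aHKO replicate 3. Spp1 rose from 42.4 ± 8.75 to 200 ± 66.2 CPM, and the collagen gene Col1a1 from 8.56 ± 2.71 to 17.8 ± 7.53 CPM (adjusted p = 0.0286), a call lost without Ctrl replicates 2 or 3 or Fam210aHKO replicate 3 (adjusted p = 0.0906, 0.0681 and 0.101) and with FPKM. Stellate cell and myofibroblast markers had 2 of 14 higher and 0 lower (also 2 and 0 adjusted over the list alone; camera adjusted p = 0.446), with 7 called higher with library totals, 1 called without Ctrl replicate 1 or 2 and 0 without Ctrl replicate 3 or Fam210aHKO replicate 3. Sinusoidal endothelial markers had 2 of 20 lower and 0 higher (0 and 0 adjusted over the list alone), with a median of -0.33 (between -0.54 and -0.21 without single libraries) that turned to 0.13 with library totals. That list missed the threshold (camera adjusted p = 0.0534). With the replicate block 8 members were lower and it was called (adjusted p = 0.0321), as it was with limma-voom (0.00773), with no filter (0.0264) and with protein-coding genes alone (0.0382); without Fam210aHKO replicate 3 also 8 were lower (adjusted p = 0.00233). It was called without Ctrl replicate 1 as well (adjusted p = 0.0206, 1 member lower), while 0 members were lower without any of Ctrl replicates 2 and 3 and Fam210aHKO replicates 1 and 2.

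Markers of blood cells were scarce. Erythroid markers had 2 of 8 lower, Alas2 (53.6 ± 12.4 and 9.53 ± 5.03 CPM) and Klf1, with 0 higher (also 2 and 0 adjusted over the list alone; camera adjusted p = 0.388, and 0.0291 without Fam210aHKO replicate 3); 2 were higher without Fam210aHKO replicate 1 or 2. Their median was 0.92 although the set test pointed lower, and it turned to -0.32 without Fam210aHKO replicate 3. With library totals 3 were higher and 2 lower, with a median of 1.37. Hba-a1, a haemoglobin gene of that list, was at 112 CPM in Fam210aHKO replicate 3 and between 7.93 and 17.7 CPM in the other 5 libraries. For T and NK cells (6 measured, median -0.42, between -0.70 and -0.12 without single libraries, and 0.03 with library totals; camera adjusted p = 0.394) and for B and plasma cells (9 measured, median -0.11, between -0.47 and 0.02 without single libraries, and 0.34 with library totals; camera adjusted p = 0.886) edgeR called 0 markers, and 2 T and NK cell markers were lower when adjusted over the list alone. Cd4 stood at 1.90 ± 0.381 and 0.938 ± 0.294 CPM (adjusted p = 0.0548, 0.0413 with the replicate block, 0.0485 without Ctrl replicate 2 and 0.0306 without Fam210aHKO replicate 3). Too few neutrophil (3), megakaryocyte and platelet (3), adipocyte (2) and pancreatic acinar (1) markers passed the filter for a set test. Of these edgeR called Adipor2 (493 ± 107 and 279 ± 66.8 CPM) and Cela1 (9.28 ± 2.14 and 5.26 ± 0.308 CPM) lower, also when adjusted over each list alone, and neither call held without Ctrl replicate 3 (adjusted p = 0.0554 and 0.076) or with library totals (0.168 and 0.192). The Adipor2 call was also lost without Ctrl replicate 2 (adjusted p = 0.0502) or Fam210aHKO replicate 1 (0.0556). An exact permutation test on the mean log2 CPM of each list of cell type markers gave p = 0.1, the smallest that 3 against 3 libraries allow, for lipid-associated macrophages, cholangiocytes, T and NK cells, adipocytes and acinar cells. For the other cell types and the sex-linked genes the exact p lay between 0.2 and 0.9.

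**Figure D3:**
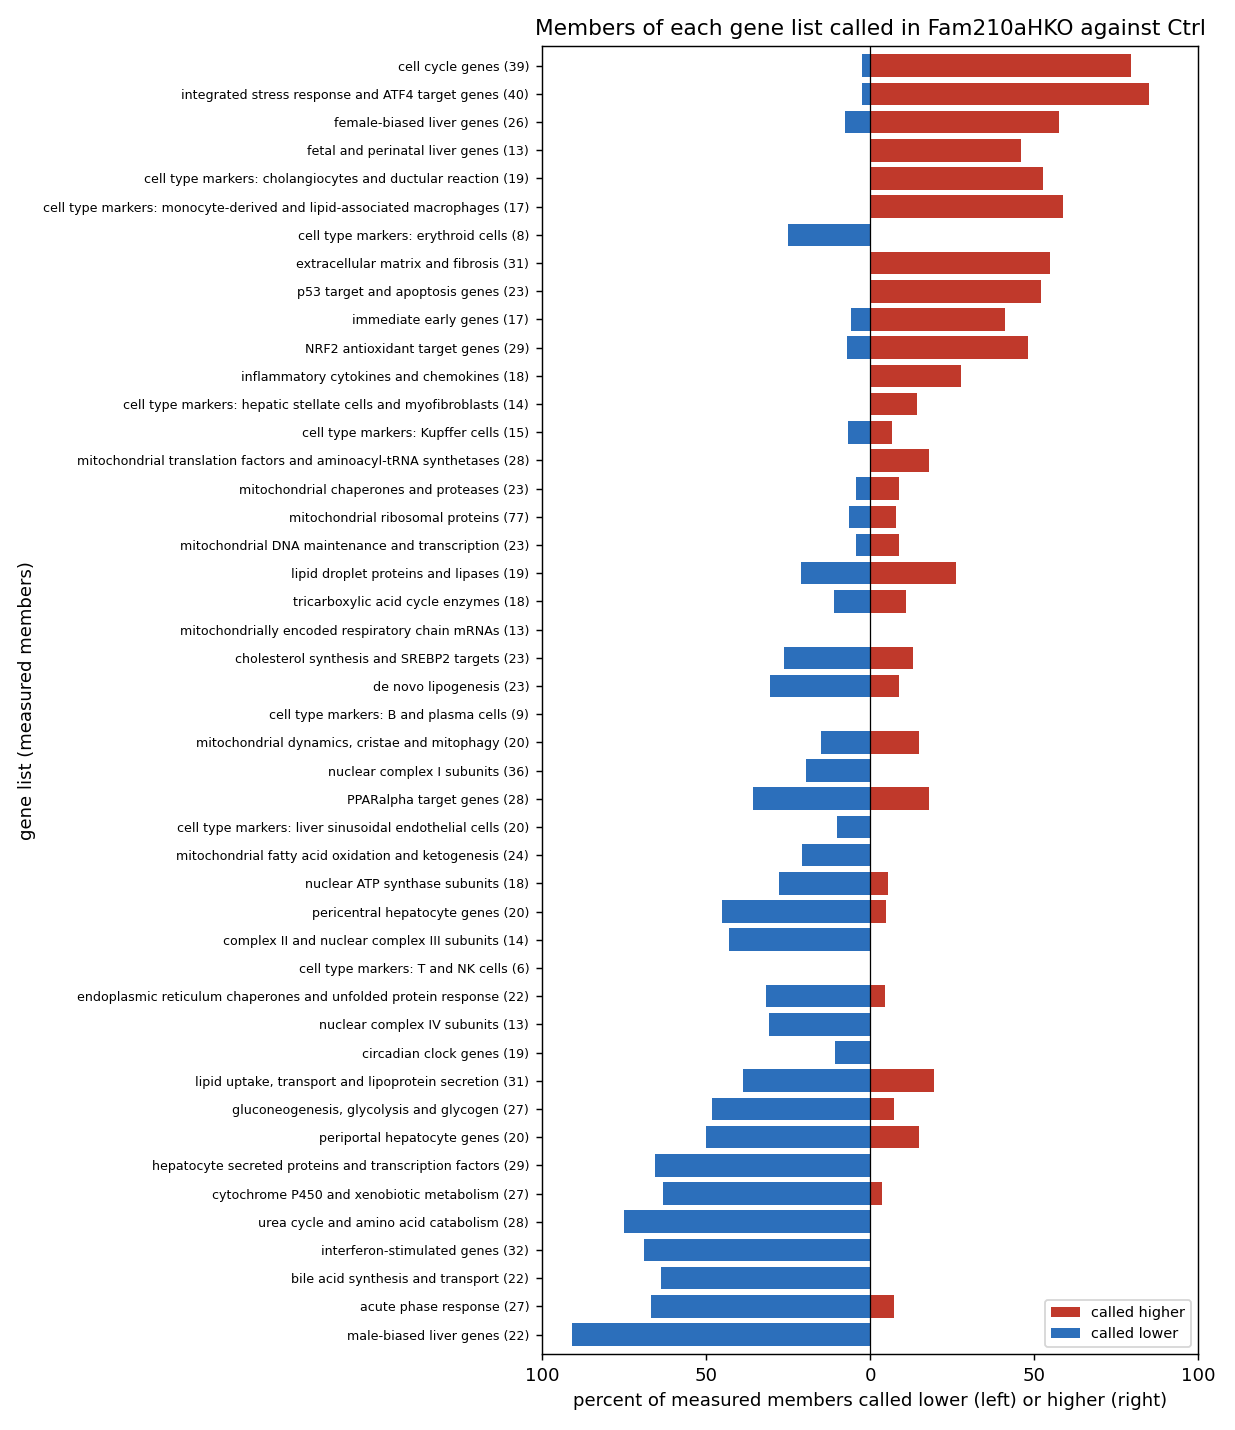
Percent of the measured members of each of the 46 tested gene lists called higher (red, right) or lower (blue, left) in Fam210aHKO, ordered by median log2 fold change, with the number of measured members in brackets. Male-biased liver genes, with 20 of 22 lower, stand at the bottom and cell cycle genes, with 31 of 39 higher, at the top; with library totals in place of TMM factors the balance shifts to the right.

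In sum over the lists, camera called 24 of 46 at its preset correlation of 0.01, 10 higher and 14 lower, and 0 with an estimated correlation, where the lowest adjusted p was 0.0988 and 14 lists had an unadjusted p under 0.05. Fry, which asks whether a set moves one way on balance, called 20, and 19 were called by both tests in the same direction. Fam210aHKO replicate 1 held 1.31% of its counts in ribosomal RNA genes against at most 0.0295% in the other libraries; without that library 1475 genes were higher and 1593 lower.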

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

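The direction of the Fam210a decrease and its side of the threshold held under every alternative; its log2 fold change lay between -2.20 (without Fam210aHKO replicate 3) and -1.87 (without Fam210aHKO replicate 2) when single libraries were left out, and was -1.54 with library totals. Among the called genes that each alternative still tested (between 3276 and 3774), 0 were called in the opposite direction.

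Scaling moved the number of genes most. With library totals 5846 genes were higher and 868 lower, against 1922 and 1852 with TMM, and 73.9% of the TMM calls were kept; the alternative's own construction, which leaves out factors averaging 0.855 and 1.17, shifted the median gene by 0.45. Median-of-ratios scaling gave 1866 and 1899. From the FPKM values 1273 genes were higher and 1864 lower with log2(FPKM + 1), and 1246 and 1844 with log2(FPKM + 0.1). With log2(FPKM + 1) and no filter 975 were higher and 1379 lower. The cause of these shifts was not tested. With a change of at least 2-fold asked as well, 1052 were higher and 950 lower, and at an adjusted p under 0.01 there were 1094 and 1068, as stricter thresholds must give fewer. DESeq2 called 1854 and 1867, limma-voom 1827 and 1806.

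Leaving out single libraries gave between 1339 (without Ctrl replicate 3) and 1897 genes higher, between 1334 (without Fam210aHKO replicate 2) and 1834 lower, and between 21 and 26 lists called. With the replicate block 2434 genes were higher, 2462 lower and 26 lists called; the block kept 3759 of the 3774 calls. Among the lists and the 206 named genes, it changed no other call than those given in the report (Scd1, Cd4 and mt-Rnr1 among the genes). Without the genes standing apart in Fam210aHKO replicate 1, a fit chosen after the data were seen, the counts were 1927 and 1862 genes and 25 lists.

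With an estimated correlation camera called 0 of the 24 lists, and the cause was not tested. Even the male-biased list, with 20 of 22 members lower, had an unadjusted camera p of 0.00482 and an adjusted p of 0.0988 at this setting. A list that it did not call is thus not shown to be unchanged. Fry called 20. Of 206 named genes 42 lost their call and 3 gained one with library totals, 39 lost it with log2(FPKM + 1) and no filter, and leaving out 1 library ended between 11 and 22 of these calls.

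Depth limits how far a fold can be bounded: 3 counts were between 0.153 and 0.239 CPM in a library, and a gene at 0 counts in a group bounds a fold only down to 3 counts. In simulated data 83% of changes of 1 log2 unit were found, which was not split by abundance. The changed genes there were drawn only from those of higher mean count, so this share does not cover genes of low counts. Nor does the share cover errors of scaling, since no difference in scaling between the groups was simulated.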

Other observations

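Growth factors of the EGF family, which act through EGFR or, in the case of neuregulins, through ERBB3 and ERBB4, in part rose; the group was chosen after values were seen. Of 15 genes 11 were tested, 4 were higher, 1 was lower and 6 were not called. Nrg1 rose from 0.369 ± 0.225 to 26.1 ± 13.1 CPM (log2 fold change 6.14, adjusted p = 1.5e-05) and Btc from 3.38 ± 0.328 to 6.77 ± 0.402 CPM, along with Areg. Tgfa rose from 18.8 ± 3.05 to 26.7 ± 1.76 CPM (adjusted p = 0.043), a call that did not hold when each library was left out in turn. The receptor gene Egfr fell from 459 ± 180 to 138 ± 18.6 CPM (log2 fold change -1.74, adjusted p = 0.000483), and Erbb3 and Erbb4 were not called.

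Imprinted genes, many of which are silenced in the liver after birth, were also looked at after values were seen. Of 11 genes 8 were tested, 3 rose and 5 were not called. H19 (log2 fold change 7.10), Grb10 (2.36) and Igf2r (0.91) rose, whereas Igf2, the neighbour of H19, had 0 counts in Ctrl and 1 in Fam210aHKO.

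In the male-biased genes the tests on female mice and on delayed maturation were written after the result was seen, and the test on STAT5 before. Female mice are excluded, since Ddx3y was at least 91.3 CPM and Xist at most 0.486 CPM in all 6 libraries. Lower growth hormone signalling through STAT5 may account for the loss: Socs2, Cish, Igf1, Igfals and Ghr had a median log2 fold change of -1.43, with Igf1 (-2.0), Igfals (-2.19) and Ghr (-1.43) called lower, Socs2 (0.26) and Cish (-0.93, adjusted p = 0.127) not called, and Stat5b lower (-0.58, adjusted p = 0.0278), while against it Bcl6, which STAT5 represses, was lower too (-1.20, adjusted p = 0.0497). Igf1 and Igfals also belong to the list of hepatocyte secreted proteins and transcription factors, of which 19 of 29 members fell. Their fall is thus not particular to STAT5. Delayed maturation stays open for the loss of male-biased genes too. Its test was written after the result was seen, so the values that follow cannot count as support. The fetal and perinatal list had a median of 1.32 (0.80 without Fam210aHKO replicate 1). Its 6 called members were all higher, and 7 of 13 were not called. Of those too low to test, Igf2 had 0 counts in Ctrl and 1 in Fam210aHKO, Dlk1 2 and 4, and Meg3 15 and 22. The data do not separate lower STAT5 signalling from delayed maturation, and STAT5 activity was not measured.

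In the interferon-stimulated genes the test on fewer macrophages was written after the result was seen, and the test on scaling before. Markers of resident macrophages and sinusoidal cells fell less than the interferon-stimulated genes, which argues against fewer such cells as the whole cause. The 95% intervals given here come from resampling the members of each list, so they do not measure the spread between libraries. Kupffer cell markers had a median log2 fold change of 0.12 (95% interval -0.17 to 0.23; -0.03 without Ctrl replicate 3, -0.18 without Fam210aHKO replicate 3 and 0.23 without Fam210aHKO replicate 1) and sinusoidal markers -0.33 (-0.39 to -0.27; -0.54 without Fam210aHKO replicate 3 and -0.21 without Fam210aHKO replicate 1), against -0.98 (-1.31 to -0.73; between -1.16 and -0.89 without single libraries) for the interferon-stimulated genes. The values argue against scaling as the whole cause, since 14 of the 22 members called lower stayed so with library totals. The median of the list was then -0.53, with the typical tested gene shifted by 0.45. For the members that lost their call, scaling stays open. Fewer T and NK cells could remain, with 6 markers at a median of -0.42 (-1.11 to 0.09), an interval that overlaps the one above, and so could a response to the knockout itself, which no test here addressed.

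The tests on Vmn2r3 were written before their results were seen, except the count expected in Ctrl. Of the 2170 genes that share a word of 31 bases, 0 had 0 counts in Ctrl and at least 100 in Fam210aHKO. Any of the 1276 with at least 100 there would, by proportion, have given Vmn2r3 at least 13.5 Ctrl counts, where it had 0. For these genes the values argue against shared reads as the source. Genes with fewer counts, inexact matches and genes whose own reads were dropped as multimapping are not covered. The share of words alone (6.52% of 17620, 1148 words) lay between the limits set beforehand and decided nothing. Of the 6 neighbours within 100 kb 0 passed the filter, so none could be called. All 6 had 0 counts in every library, which argues against activation together with a neighbour. A strain-derived segment around Fam210a is excluded by position alone, since Vmn2r3 lies on chromosome 3 and Fam210a on 18. Of 34 genes within 5 Mb of Fam210a 20.6% were called, against 27.6% elsewhere (Fisher's exact p = 0.445). A strain-derived segment on another chromosome than that of Fam210a was not tested. A response to the knockout itself and reads from unannotated sequence or an introduced construct were not tested.

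Chance was examined with the 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05. For genes 1 of the 10 splits, the real one, called as many as 3774, and the highest other value was 0, also among the 4 splits that part 3 pairs. For gene lists 3 of the 10 called at least the real 24, with 26 the highest; among the splits that part 3 pairs the highest other was 24. Each of the other splits keeps part of the real difference and adds the rest to the spread, so neither count is a value for no change. Scaling stays open for part of the genes. With library totals 2790 of the 3774 calls (73.9%) were kept and 0 were reversed, which argues against scaling for those kept. That share is below the one set beforehand for excluding scaling for the genes as a whole.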
